A study of Mus musculus with 48 samples.

How the data were processed

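Chromatin immunoprecipitation on tiling arrays (ChIP-chip) and array hybridisation of cDNA were used in 2 mouse embryonic stem (ES) cell lines, the male line E14 and the female line LF2. Cells were sampled undifferentiated, after 4 days of all-trans retinoic acid (atRA) and as 10-day embryoid bodies (EB). The 8 assays were H3K4me3, H3K27me3, H3K36me3, H3K9me2, core histone H3, the TATA-binding protein TBP, RNA polymerase II (RNAPII) and cDNA. With 2 lines and 3 conditions this gives 48 arrays in 48 groups, 1 array per group. Groups were taken from the sample titles.

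Per the labels, the immunoprecipitated DNA or the cDNA was labelled with Cy5 and genomic input DNA with Cy3, precipitated material went through T7 amplification, and cDNA was made with hexamers together with oligo(dT). The array names inside the deposited ratio files differ on the last point. They give a column step and N6 for the 3 E14 cDNA arrays and for undifferentiated LF2 cells, and dT with N6 for atRA-treated LF2 cells and LF2 embryoid bodies. Which of these sources is right was not settled. The scanner files hold 1 intensity per probe and dye, extracted without normalization by NimbleScan 2.3.31 or 2.3.78 per the file headers. The authors also deposited a log2 ratio of Cy5 over Cy3 for each probe. On the 47 arrays with usable scanner files the deposited ratios equal the log2 ratio of the scanner intensities minus 1 constant per array, to within 0.0050, and the headers of most of these files name that constant as a biweight mean. The series-wide table holds the same values, and its column medians lie between -0.05 and 0.02. Probe positions are in mouse build mm8, as the array design's name in the file headers states. No antibody titration, peak caller or mapping of probes to genes is given in the sources used here.

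For 47 arrays the main value was log2 of the signal at 635 nm (Cy5) over that at 532 nm (Cy3), with no background correction, loess or quantile step, centred on the array's median over all 385467 probes. The scanner files listed for cDNA of atRA-treated LF2 cells name another array design and were not used. The deposited ratios of that sample, which name the common design, took their place with the same centring. On the arrays used, 318373 probes lie on the X between 93.9 and 165.6 Mb with a median spacing of 100 bp. Other probes include 9441 on the Y, 53539 on unplaced Y sequence and 159 on mitochondrial DNA.

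The design called for exons, promoters and gene bodies, or for fixed windows should no annotation of mm8 be given. The reference tables at hand are of another build, so features were 10 kb windows with at least 10 probes, and each value is the mean over a window's probes. Of 7068 windows holding any probe, 6645 were kept, with a median of 47 probes. Windows are named by their start in Mb, adjacent windows were merged, and no window was given a gene name. The fixed gene lists, which include X-inactivation-centre, escape, pluripotency, neural, blood and housekeeping genes, could not be placed on the windows, and neither could the parts of the naming rule that name single genes. No list was tested. With an input signal per window, 681 windows lay more than 1.0 log2 above the X median input. These are called high-input windows. They may hold repeated or multicopy sequence, but neither was measured. Of the windows and merged stretches named in the results, those that start at 95.34, 97.47, 97.48, 97.49, 97.61, 97.99, 98.16, 98.28, 99.34, 99.65, 118.72, 119.12, 119.31, 119.78, 119.99, 120.71, 120.99, 129.83, 130.03, 130.39, 135.15, 137.92, 147.92, 148.00, 165.32 and 165.33 Mb are high-input.

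The tested comparisons, 9 in all, were EB against undifferentiated cells, atRA against undifferentiated cells, and LF2 against E14, each for cDNA, H3K4me3 and H3K27me3. Each used the 6 arrays of 1 assay in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, cell line plus condition, 2 residual degrees of freedom) with Benjamini-Hochberg adjustment over the 6645 windows and a threshold of 0.05. The spread in these tests is how far the change differs between the lines, and nothing in the labels speaks of separate cultures. A p-value therefore measures only the spread between these arrays, and a change present in 1 line alone counts as spread. The female minus male change, (LF2 EB minus LF2 undifferentiated) minus (E14 EB minus E14 undifferentiated), has no residual degrees of freedom and was not tested. Its median over a set of windows was taken for 5 assays, with a 95% interval from 2000 resamples of 1 Mb blocks that covers the sampling of windows and not the spread between arrays. In place of genes, the sets were windows with a mean H3K4me3 ratio above 1 (60 windows) for H3K4me3, and the upper tercile of windows by mean cDNA ratio (2215 windows) for cDNA, RNAPII and H3K36me3. For H3K27me3 the median over the upper tercile was taken minus that over the lower tercile.

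The windows named in a tested comparison were the 5 with the highest and the 5 with the lowest log2 change among those with an adjusted p under 0.05 and the same sign in both lines (in all 3 conditions for LF2 against E14), and otherwise the 3 highest and 3 lowest of the same sign, as values. For the female minus male change they were the 5 highest and 5 lowest of the set. This rule, the tests and all alternatives, except those said to be chosen after seeing the data, were fixed before the data were examined. The limma step was tested on simulated data drawn from each assay's fitted spread for the EB comparison, with 200 of 6645 windows changed. At 1 log2 it recovered 81.5% of them for cDNA, 64.5% for H3K4me3 and 99.5% for H3K27me3, and at 2 log2 95%, 96.5% and 100%. False calls made up 4.1% to 8.2% of the calls. The simulated windows were independent and changed equally in both lines, so these shares are not the power or error rate on the real arrays.

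Arrays have no read depth, and their number limits the precision. Median signals per array ran from 306.2 to 1094.0 in the input channel and from 358.6 to 1500.2 in the Cy5 channel. Medians of 3840 random-sequence control probes ran from 167.4 to 1000.6 in the input and from 221.1 to 1375.6 in Cy5, so that a large part of each signal is background and ratios are compressed. Ratios over mitochondrial probes were above 0 on all 6 cDNA arrays and below 0 on all 42 ChIP arrays. Over all probes, 1 of the 15 H3K9me2 array pairs, undifferentiated E14 against E14 embryoid bodies, had r = -0.45. No other pair within an assay lay below -0.3 over probes. Over windows 4 H3K9me2 pairs did, each an E14 array from undifferentiated or atRA-treated cells against an embryoid body array (-0.45 to -0.64), while the embryoid body arrays of the lines had r = 0.74 with each other, and so did 1 TBP pair, E14 embryoid bodies against LF2 atRA (-0.33). The dyes stated in the labels were kept. Among the core H3 arrays undifferentiated LF2 stands apart in its spread, with a standard deviation over windows of 0.272 against 0.089 to 0.125. Its r over windows with undifferentiated E14 and both embryoid body arrays was -0.16 to -0.26. That of LF2 atRA with the same arrays was -0.14 to -0.20, and undifferentiated LF2 and LF2 atRA had r = 0.78 with each other.

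The alternatives fixed beforehand were the authors' deposited ratios, normexp background correction with offset 50 followed by loess, scaling each array to one median absolute deviation, centring on the mode, at least 6 probes per window, leaving out probes in the lowest 10% of input signal on any array, the ratio minus that of the core H3 array, the median over probes, and leaving out each array in turn. Alternatives chosen after seeing the data were centring on X probes alone, 2 kb and 50 kb windows, at least 30 probes per window, leaving out high-input windows, an eBayes spread that follows the mean level, the day of image extraction as a block, and the arrays of 1 extraction day alone. Alternatives fixed for exons, promoters of other widths, gene bodies and gene lists were not run, since they need gene positions. Without scanner values, cDNA of atRA-treated LF2 cells kept its deposited ratios under normexp, and the other 5 arrays decided which dim probes to leave out. Image extraction fell on 16 days. Windows, intervals and figures were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.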

Results

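Chromatin and transcripts of the mouse X chromosome were profiled in male E14 and female LF2 ES cells, before differentiation, after 4 days of atRA and in 10-day embryoid bodies, aggregates in which ES cells differentiate. The title of the series names X inactivation, by which female cells silence an X chromosome as they differentiate. LF2 cells are thus the line in which it can occur and E14 cells, with a single X, the comparison. With 1 line of each sex, sex and cell line cannot be told apart. Female minus male therefore stands for LF2 minus E14 throughout. H3K4me3 marks active promoters, H3K27me3 is the mark of Polycomb repression, and H3K36me3 covers transcribed gene bodies. H3K9me2 is a repressive mark, while TBP and RNAPII mark the transcription machinery. Each of the 48 combinations of 8 assays, 2 lines and 3 conditions has 1 array and therefore no replicate of its own. Values are log2 ratios to input DNA, as means over 10 kb windows, and a ratio of 0 is the array's median. Most probes lie on the X, so this centring removes a shift shared by the whole chromosome, and such a shift cannot be seen here. The windows, 6645 in all, cover the X from 93.9 to 165.6 Mb (mm8).

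H3K27me3 rose on differentiation in 1 window, at 99.65 Mb, which had high H3K4me3 and cDNA ratios in the undifferentiated cells of both lines. The window spans positions 99650001 to 99660000 of the X. Its input signal lies 1.91 log2 above the X median, which makes it a high-input window, and it was not tested where such windows were left out. Its H3K27me3 ratio rose by 1.74 log2 in embryoid bodies (SE 0.11, limma adjusted p 0.00111), by 1.58 in E14 and 1.90 in LF2. It went from -0.24 through 0.65 with atRA to 1.34 in E14, and from -0.89 through 0.18 to 1.01 in LF2. H3K4me3 over the same window was 2.79 in undifferentiated E14 cells and 0.94 in their embryoid bodies, and 2.91 and 1.41 in LF2. Its cDNA ratio was 2.69 and 0.75 in E14, and 3.47 and -0.02 in LF2. Core H3 was higher in embryoid bodies too, with -0.44 and -0.26 in E14 and -1.30 and -0.51 in LF2, where the undifferentiated core H3 array has a larger spread than the others. After subtracting core H3 the H3K27me3 rise was 1.26 log2 (limma adjusted p 0.00155).

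After 4 days of atRA, H3K27me3 had risen in the same window by 0.98 log2 (0.89 in E14, 1.07 in LF2) and had fallen in 3 windows. At 99.69 Mb the change was -1.19 (-1.09 in E14, -1.30 in LF2) and at 99.73 Mb it was -1.04 (-1.04 and -1.03). At 158.09 Mb it was -1.32 (-1.50 and -1.15). All 4 windows had a limma adjusted p of 0.0321 and moved the same way in both lines. After subtracting core H3 the atRA change at 99.65 Mb was 0.52 and no longer passed (limma adjusted p 0.348). The windows at 99.69 and 99.73 Mb lie in a stretch of raised H3K27me3 from 99.69 to 100.25 Mb, whose 45 windows were chosen, after the values were seen, for a mean ratio above 0.3 in the undifferentiated cells. Their mean H3K27me3 ratio was 0.66 in undifferentiated E14 cells, 0.16 after atRA and 0.19 in embryoid bodies. In LF2 it was 0.64, 0.24 and 0.54. A choice by the undifferentiated ratio itself favours a fall afterwards. The spread of the H3K27me3 arrays fell as well, with a standard deviation over all windows of 0.308, 0.156 and 0.147 in E14. In LF2 that standard deviation was 0.241, 0.205 and 0.199. The difference between the lines in the ratio of the stretch in embryoid bodies was not tested. It was not seen all along the stretch, and the arrays also differ in how far their H3K27me3 ratio follows the input signal, with r from 0.57 to 0.22 in E14 and from -0.06 to 0.48 in LF2 between undifferentiated cells and embryoid bodies.

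At an unadjusted p under 0.05, 647 windows differed in H3K27me3 in embryoid bodies and 352 after atRA. The call at 99.65 Mb in embryoid bodies was lost with centring on X probes (limma adjusted p 0.056) or on the mode (0.0767), with log2 changes of 1.69 and 1.73. It held in the other 15 of the 17 alternatives in which the window was tested, but many of these could say little. The deposited ratios and the probe minimums leave the window's own values as they were. Fits without 1 array have only 1 residual degree of freedom. All 4 atRA calls were lost with X centring (limma adjusted p 0.296), with log2 changes of 0.95, -1.22, -1.07 and -1.35. The atRA count was 0 as well with a spread following the mean, mode centring, no dim probes, 2 kb and 50 kb windows and at least 30 probes, with 41 to 1045 windows at an unadjusted p under 0.05 in limma. Leaving out 1 array raised the count in embryoid bodies from 1 to 361 without undifferentiated E14, 428 without undifferentiated LF2, 46 without either atRA array, 80 without E14 embryoid bodies and 115 without LF2 embryoid bodies. After atRA the count went from 4 to 146 without undifferentiated E14, 361 without undifferentiated LF2, 33 without E14 atRA, 26 without LF2 atRA and 93 without either embryoid body array. Both embryoid body arrays were extracted on 1 day and the other 4 on another, so that the embryoid body change and the day cannot be told apart. Within the other day, which is the same fit as without an embryoid body array, 93 windows differed after atRA, 6 higher and 87 lower.

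**Figure D1:**
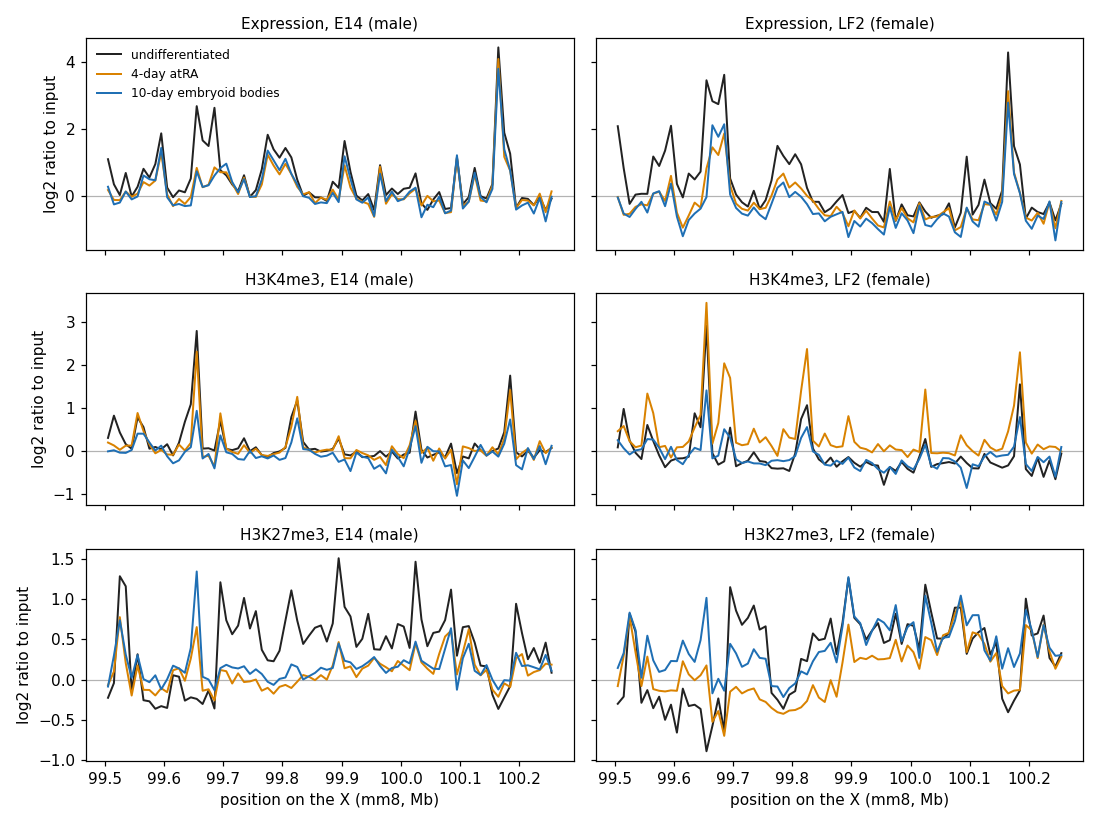
Log2 ratio to input (vertical axes) of cDNA (marked Expression), H3K4me3 and H3K27me3 in 10 kb windows from 99.50 to 100.25 Mb of the X in mm8 (horizontal axes), for E14 on the left and LF2 on the right, with 1 line per condition and 1 array per line. At 99.65 Mb H3K27me3 rises to 1.34 in E14 and 1.01 in LF2 embryoid bodies, while cDNA from 99.66 to 99.69 Mb is 2.02 in LF2 and 0.41 in E14 embryoid bodies.

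Next to this window, 3 windows from 99.66 to 99.69 Mb had a higher cDNA ratio in the embryoid bodies of the female line than in those of the male line. Their mean cDNA ratio was 3.08 in undifferentiated LF2 cells, 1.53 after atRA and 2.02 in embryoid bodies. In E14 it was 1.94, 0.50 and 0.41. H3K4me3 at 99.68 Mb was -0.23 in undifferentiated LF2 cells, 2.04 after atRA and 0.51 in embryoid bodies, against 0.02, -0.35 and -0.40 in E14. H3K36me3 over the 3 windows was 0.62 in LF2 and 0.19 in E14 embryoid bodies. The H3K4me3 array of atRA-treated LF2 cells stands apart from the other 5, with a median of 2.27 over the 60 windows rich in H3K4me3 against 0.59 to 1.38, and the value of 2.04 rests on it. The windows were picked after their values were seen, with 1 array per value and no test. The female minus male change of cDNA at 99.66 Mb, 0.67, turned to -0.18 with the arrays scaled to one spread.

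H3K27me3 differed between LF2 and E14 in 3 windows in the same direction in all 3 conditions. It was higher in LF2 at 165.32 Mb, by 0.94 log2 (SE 0.09, limma adjusted p 0.0202). It was lower in LF2 at 118.72 Mb, by -0.72 (SE 0.08, limma adjusted p 0.0398), and at 130.39 Mb, by -1.31 (SE 0.13, limma adjusted p 0.0202). All 3 windows have raised input signal, which at 130.39 Mb lies 5.71 log2 above the X median. In this comparison 305 windows had an unadjusted p under 0.05. None of the 3 passed with X centring, where their log2 differences were 0.92, -0.74 and -1.32. The count was also 0 with mode centring, no dim probes, 2 kb and 50 kb windows and at least 30 probes, with 59 to 832 windows at an unadjusted p under 0.05 in limma. Without an undifferentiated array of either line 22 windows passed, while 14 passed without an embryoid body array.

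Differentiation changed cDNA ratios in no window by limma's adjusted p, in either condition. The lowest values in embryoid bodies lay at 99.65 Mb, with a change of -2.72 log2 (SE 0.38; -1.95 in E14, -3.49 in LF2), at 97.28 Mb with -2.54 (SE 0.50; -1.65 and -3.43) and at 100.28 Mb with -2.18 (SE 0.49; -1.51 and -2.85). The highest lay at 140.74 Mb with 0.96 (SE 0.07; 0.89 in E14, 1.03 in LF2) and at 128.44 Mb with 0.89 (SE 0.14; 1.04 and 0.74). At 135.15 Mb the change was 0.89 as well (SE 0.39), but nearly all of it came from E14 (1.69 in E14, 0.08 in LF2). After atRA the lowest were 97.28 Mb with -2.90 (SE 0.50), 99.65 Mb with -2.24 (SE 0.38) and 139.58 Mb with -2.13 (SE 0.29), and the highest 135.01 Mb with 0.70, 98.16 Mb with 0.55 and 165.03 Mb with 0.47. At an unadjusted p under 0.05 limma gave 1591 windows in embryoid bodies and 796 after atRA. The smallest limma adjusted p was 0.0566 in embryoid bodies, at 140.74 Mb, and 0.263 after atRA. Both differentiated LF2 cDNA arrays carry another priming in their names. Their mitochondrial cDNA ratios were 0.760 and 0.765, against 3.255 in undifferentiated LF2 cells. Within LF2, differentiation and priming therefore cannot be told apart.

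These cDNA counts of 0 depend on single arrays and on the centring. Without undifferentiated E14, 1823 windows passed in embryoid bodies (170 higher, 1653 lower) and 1329 after atRA, and without undifferentiated LF2 598 and 181. With X centring 133 windows passed in embryoid bodies, 2 higher and 131 lower, and with mode centring 179.

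The cDNA ratio differed between LF2 and E14 in 495 windows, 132 higher and 363 lower in LF2. Of the higher ones, 126 lie between 119.11 and 121.79 Mb. The highest were 119.31 to 119.33 Mb with 2.00 log2 (SE 0.14), 119.99 Mb with 1.96 (SE 0.18), 119.78 Mb with 1.92 (SE 0.10) and 119.12 Mb with 1.91 (SE 0.08), with limma adjusted p from 0.00885 to 0.0208. In 123 of the 132 higher windows the input signal of the male line lies more than 0.5 log2 above that of the female line, against 1 of the 363 lower windows. The lowest were 165.31 Mb with -1.80 (SE 0.19), 99.90 Mb with -1.79 (SE 0.16), 102.64 Mb with -1.60 (SE 0.14), 102.62 Mb with -1.55 (SE 0.10) and 148.00 Mb with -1.55 (SE 0.13), with limma adjusted p from 0.00893 to 0.0287. These named windows have the same sign in all 3 conditions and passed with X and mode centring as well.

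Of the 3 LF2 cDNA arrays, those of atRA-treated cells and embryoid bodies carry another priming in their names and had mitochondrial cDNA ratios of 0.760 and 0.765, against 2.416 to 3.289 on the other 4, so that line and priming are partly confounded in this comparison. The count of lower windows depends on the centring. The X median after centring on all probes was 0.107, 0.109 and 0.151 on the E14 cDNA arrays (undifferentiated, atRA, EB) and -0.014, -0.040 and 0.004 on the LF2 arrays. The centring includes 53539 probes on unplaced Y sequence. Their median cDNA ratio was -2.827, -3.172 and -3.562 on the E14 arrays and 0.047, 0.180 and -0.058 on the LF2 arrays. They thus lower the E14 centre and raise the E14 ratios over the X. Relative to the X median, 174 windows passed, 133 higher and 41 lower. Leaving out either undifferentiated array gave 3028 windows, and leaving out either atRA array or either embryoid body array gave 0 by limma, with 929 and 1593 windows at an unadjusted p under 0.05. The 3 E14 cDNA arrays share 1 extraction day, undifferentiated LF2 cells and LF2 embryoid bodies each have another, and the day of the LF2 atRA array is not known, so that line and day cannot be told apart.

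H3K4me3 changed in no window by limma's adjusted p, in embryoid bodies, after atRA or between the lines. In embryoid bodies the lowest values were at 99.65 Mb with -1.68 log2 (SE 0.26; -1.85 in E14, -1.50 in LF2), 97.28 Mb with -1.57 (SE 0.20; -1.82 and -1.33) and 154.86 Mb with -1.42 (SE 0.12; -1.30 and -1.54). The highest were 120.33 Mb with 0.59 (0.03 in E14, 1.15 in LF2), 94.69 Mb with 0.40 (0.35 and 0.45) and 151.71 Mb with 0.39 (0.45 and 0.33). After atRA the lowest were 154.86 Mb with -1.35 (SE 0.12), 139.58 Mb with -1.19 (SE 0.18) and 97.28 Mb with -0.91 (SE 0.20). The highest after atRA were 164.14 Mb with 1.52, 164.01 Mb with 1.35 and 97.99 Mb with 1.33, each with SE 0.60, and their changes were 0.31 to 0.43 in E14 and 2.29 to 2.61 in LF2. They rest on the LF2 atRA array, whose r over windows with the E14 and LF2 embryoid body arrays was 0.21 and 0.23, and why it stands apart was not tested. Between the lines the highest values in LF2 were at 147.92 to 147.94 Mb with 1.25, where input lies 3.69 log2 above the X median, and 97.99 Mb with 0.85, and the lowest at 119.48 Mb with -0.48, 119.25 Mb with -0.43 and 136.72 Mb with -0.43.

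At an unadjusted p under 0.05 limma gave 181 windows for H3K4me3 in embryoid bodies, 162 after atRA and 279 between the lines. Normexp with loess gave 54 windows in embryoid bodies, 53 of them lower, and 8 after atRA, all lower. It called the named lower windows of both comparisons, with limma adjusted p from 0.000804 to 0.00589. Undifferentiated E14, E14 atRA and LF2 atRA were extracted on 1 day, undifferentiated LF2 on another and both embryoid body arrays on the third. The embryoid body change and the day cannot be told apart.

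Promoter-like windows, those 60 with a mean H3K4me3 ratio above 1, had less H3K4me3 in the embryoid bodies than in the undifferentiated cells of both lines, in values that were not tested. Their median ratio was 1.33 in undifferentiated E14 cells, 1.38 after atRA and 0.75 in embryoid bodies, and 1.32, 2.27 and 0.59 in LF2. The female minus male change in embryoid bodies was -0.12 (95% interval -0.17 to -0.08), from -0.73 in LF2 and -0.61 in E14, and 49 of the 60 windows were below 0. The lowest were 95.09 Mb with -0.57, 102.39 Mb with -0.46, 155.48 Mb with -0.43, 100.61 Mb with -0.42 and 164.01 Mb with -0.39. The highest were 99.65 Mb with 0.35, 100.18 and 137.92 Mb with 0.26 each, 152.83 Mb with 0.24 and 154.87 Mb with 0.14. Scaling the arrays to one spread turned the median to 1.05 and mode centring to 0.03. The direction of the named windows did not hold either, since the 5 lowest turned to between 0.57 and 1.5 with one spread and the 5 highest to between -0.77 and -0.17 with normexp and loess. Over the same 60 windows the median cDNA ratio was 1.05, 0.83 and 0.85 in E14 and 1.14, 0.18 and 0.06 in LF2. The low LF2 values come from the pair of cDNA arrays whose names give another priming and whose mitochondrial cDNA ratios were 0.760 and 0.765, against 2.416 to 3.289 on the other 4.

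The H3K27me3 contrast, upper minus lower tercile of windows by mean cDNA ratio (2215 each), fell from undifferentiated cells to embryoid bodies in LF2. In E14 it rose, and neither change was tested. The upper tercile had median cDNA ratios of only 0.18 to 0.39 per array. Its median input signal was -0.07 log2 relative to the X median, against 0.61 in the lower tercile. It is therefore not shown to hold mostly transcribed windows. The contrast was -0.30, -0.17 and -0.12 in E14 (undifferentiated, atRA, EB) and 0.03, -0.19 and -0.16 in LF2. The female minus male change of the contrast in embryoid bodies was -0.33 (95% interval -0.46 to -0.25). Of the upper-tercile windows, 77.92% had an own female minus male change below 0. Single windows ranged from -0.88 at 117.83 Mb, -0.80 at 124.05 Mb, -0.79 at 118.10 Mb and -0.76 at both 118.02 and 118.12 Mb to 1.37 at 95.34 Mb, 1.23 at 97.47 Mb, 1.20 at 95.24 Mb, 1.17 at 97.49 Mb and 1.15 at 99.34 Mb. The 5 highest of these windows have an input signal 0.96 to 1.52 log2 above the X median and the 5 lowest one of -0.45 to -0.18, so that the named windows part by input as well. Subtracting the core H3 arrays brought the change of the contrast to -0.005, and normexp with loess to -0.094. The value of -0.005 rests on the undifferentiated LF2 core H3 array, with medians of 0.09 and -0.24 over the upper and the lower tercile.

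For cDNA over the upper tercile of windows by mean cDNA ratio the female minus male change was -0.05 (95% interval -0.13 to 0.00). Outside that interval, it was -0.157 with normexp and loess and -0.214 without dim probes. Single windows reached far lower values, with -2.90 at 97.61 to 97.63 Mb, -2.81 at 130.03 Mb, -2.79 at 98.28 Mb and -2.78 at 165.33 Mb, the last with input 4.52 log2 above the X median. The highest were 155.43 Mb with 0.94, 114.52 Mb with 0.75, 99.66 Mb with 0.67 and both 126.11 and 127.98 Mb with 0.58. Over all 6645 windows, and not the upper tercile alone, a change below -1 was found in 296 and one above 1 in 0. Mitochondrial cDNA ratios, outside the X, were 0.760 and 0.765 on the LF2 atRA and embryoid body arrays and 2.416 to 3.289 on the other 4 cDNA arrays, and the array names of the same pair differ from the others in the priming they give.

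RNAPII and H3K36me3 over the upper tercile of windows by mean cDNA ratio had embryoid body changes of similar size in both lines, which were not tested. A change shared by the whole X would not show in these values, since each array is centred mostly on X probes. For RNAPII the change was -0.15 in LF2 and -0.15 in E14, and the female minus male change 0.01 (95% interval -0.01 to 0.03), whose sign turned under 5 alternatives. Both RNAPII embryoid body arrays were extracted on 1 day, apart from the other 4, and their standard deviation over windows was 0.153 in E14 and 0.147 in LF2, against 0.309 and 0.292 on the undifferentiated arrays. The lowest windows were 147.36 Mb with -1.13, 100.16 to 100.18 Mb with -1.10 and 158.11 to 158.13 Mb with -1.02. Embryoid body ratios there were 0.20 in LF2 and 0.22 in E14, 0.58 and 0.46, and 0.56 and 0.55, in that order. Undifferentiated ratios were 1.01 and -0.10, 1.78 and 0.56, and 1.39 and 0.37. These differences thus lie mainly in the undifferentiated arrays, which were extracted on different days in the lines. The highest windows were 97.48 and 148.00 Mb with 0.80 each, 128.14 Mb with 0.70, 97.99 Mb with 0.65 and 129.83 Mb with 0.63. For H3K36me3 the female minus male change was 0.01 (95% interval 0.00 to 0.03), and X centring turned it to -0.004. Its highest windows were 120.99 Mb with 0.71, 120.71 Mb with 0.69, 148.00 Mb with 0.67 and 99.65 to 99.67 Mb with 0.65, and its lowest 165.33 Mb with -0.57, 115.96 and 164.86 Mb with -0.52 each, 115.70 Mb with -0.50 and 117.42 Mb with -0.46.

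**Figure D2:**
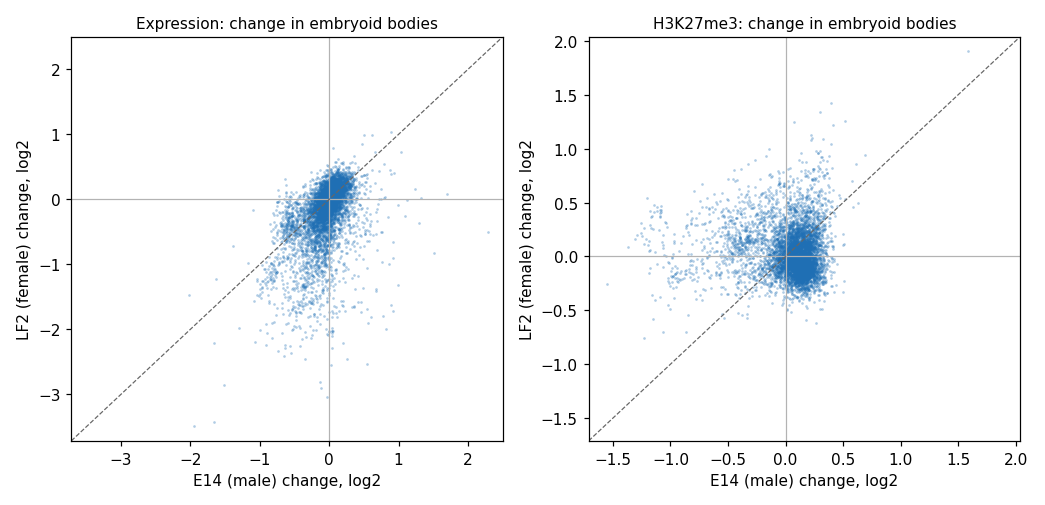
Change in embryoid bodies against undifferentiated cells (log2) in E14 (horizontal axes) and LF2 (vertical axes), for cDNA (marked Expression, left) and H3K27me3 (right), with 1 point per 10 kb window, 1 array per line and condition, and a dashed line where both changes are equal. Across the 6645 windows r is 0.47 for cDNA and -0.04 for H3K27me3, and for cDNA many windows lie below the dashed line.

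The 60 promoter-like windows had a TBP ratio of 0.77, 0.50 and 0.31 in E14 and 0.36, 0.14 and 0.21 in LF2. The TBP embryoid body arrays were likewise extracted on 1 day, apart from the other 4, with a standard deviation over windows of 0.106 in E14 and 0.070 in LF2 against 0.269 and 0.226 on the undifferentiated arrays, and no TBP change was tested. The RNAPII ratio of the 60 windows was 0.53, 0.71 and 0.71 in E14 and 0.87, 0.46 and 0.77 in LF2.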

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

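All tests of explanations given here were chosen only after the results were seen, and so was the smallest move of 0.3 log2 that each line had to make for opposite moves of single windows to be listed.

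In the values that follow, the E14 array and the LF2 array moved in opposite directions between undifferentiated cells and embryoid bodies, and the difference between the lines was not tested. For the H3K27me3 contrast, upper minus lower tercile of windows by mean cDNA ratio, the female minus male change was -0.33 (-0.17 in LF2, 0.16 in E14). For H3K27me3 in single windows it was 1.20 at 95.24 Mb (LF2 from -0.32 to 0.49, E14 from 0.58 to 0.19) and 1.23 at 97.47 Mb (LF2 from -0.22 to 0.50, E14 from 0.33 to -0.17). It was -0.79 at 118.10 Mb, -0.76 at 118.12 Mb and -0.80 at 124.05 Mb, where LF2 was lower and E14 higher in embryoid bodies. The higher of these H3K27me3 windows have an input signal of 0.96 and 1.16 log2 relative to the X median and the lower ones of -0.33 to -0.18. For cDNA it was -2.90 at 97.61 to 97.63 Mb (LF2 from 1.84 to -0.66, E14 from 1.12 to 1.52), -2.79 at 98.28 Mb (LF2 from 0.69 to 0.19, E14 from 0.14 to 2.43) and -2.81 at 130.03 Mb (LF2 from 2.84 to 0.85, E14 from 2.28 to 3.10). For RNAPII it was 0.80 at 148.00 Mb (LF2 from -0.29 to 0.16, E14 from 0.30 to -0.05) and -1.13 at 147.36 Mb (LF2 from 1.01 to 0.20, E14 from -0.10 to 0.22).

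Outside the measured windows, input signal over probes on unplaced Y sequence was 9.80 times that over X probes in the median of the 24 E14 arrays (2.36 to 25.52), and 0.89 times in the median of 23 LF2 arrays (0.79 to 1.06). No group has more than 1 array, so no single array could be tested as an outlier of its group.

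The first pattern is the lower cDNA signal of LF2 embryoid bodies beyond that of E14, found in 296 windows chosen for it, whose median cDNA ratio went from 1.40 to -0.03 in LF2 and from 1.19 to 1.23 in E14. Silencing of transcription in the female cells would lower RNAPII over these windows too, but the median female minus male change of RNAPII was 0.001 (95% interval -0.10 to 0.10) in embryoid bodies, while after atRA it was -0.28. Different priming of the LF2 atRA and embryoid body cDNA, as the array names give it, may also contribute, since mitochondrial cDNA, which is not on the X, was lower on this pair of arrays than on the other 4 by at least 1.65 log2. Priming, line and differentiation coincide on these arrays. The RNAPII interval reaches -0.10, and the standard deviation over windows was lower on the RNAPII embryoid body arrays (0.153 and 0.147) than on the undifferentiated ones (0.309 and 0.292). The explanations therefore cannot be told apart. H3K36me3 over the same windows did not fall more in LF2, with a female minus male change of 0.12 (95% interval 0.08 to 0.17), and 0.14 after atRA. For H3K4me3 it was 0.16 (0.13 to 0.21), and after atRA 0.58, which rests on the LF2 atRA array that stands apart. These windows held little H3K4me3, with medians of -0.01 and -0.16 in E14 and -0.20 and -0.19 in LF2 (undifferentiated, EB). The H3K4me3 values therefore say nothing about silencing.

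The second pattern is the higher cDNA ratio of LF2 between 119.11 and 121.79 Mb. More RNA in the female line is not what the cDNA channel shows, since the Cy5 signal itself over the 132 higher windows was lower in LF2, by -0.42 log2 in the median (95% interval -0.44 to -0.39 over windows; 2 arrays per line). A raised input signal of the male line, possibly from sequence it holds in more copies, has the values it needs: on the ChIP arrays 93.2% of the higher windows had an E14 input more than 0.5 log2 above that of LF2, against 2.0% of all windows. Across windows the input difference and the cDNA ratio difference between the lines had r = 0.78. Copy number itself was not measured, and a difference between the lines in sequence remains untested.

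The third pattern is the opposite movement of the H3K27me3 contrast between the upper and the lower tercile of windows by mean cDNA ratio. A lower contrast in female than in male embryoid bodies is there, but too small to account for the pattern. The embryoid body contrasts differed by -0.04 (95% interval -0.07 to -0.01 over windows). Most of the -0.33 lies in the undifferentiated arrays, with -0.30 in E14 and 0.03 in LF2. Ratios that follow the input signal to a different extent on each array may contribute, since r with input across windows was 0.57 for undifferentiated E14 and -0.06 for undifferentiated LF2. After each array was regressed on input the change was -0.07 (95% interval -0.11 to -0.03). Input signal also differs between the sets, with medians of -0.07 and 0.61 over the upper and the lower tercile. The regression can therefore remove a true difference, and the explanation cannot be told apart from one in undifferentiated cells.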

How the results depend on the processing

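Tests chosen only after seeing the data are centring on X probes, 2 kb and 50 kb windows, at least 30 probes per window, high-input windows left out, a spread following the mean, and the extraction day as a block or alone.

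With at least 6 probes per window, all 14 results stayed, with counts within a factor of 1.5 and no sign turned. They stayed with the deposited ratios too. Once centred, these equal the main values up to rounding, so that this agreement was given in advance and tells nothing about the processing. Counts in this paragraph are of windows past limma's threshold. For cDNA in embryoid bodies the 0 became 179 with mode centring, 117 with the median over probes, 133 with X centring and 34 with 50 kb windows, and leaving out 1 array gave 0 to 1823 (684 to 1023 at an unadjusted p under 0.05 where 0). For cDNA after atRA leaving out 1 array gave 0 to 1329 (161 to 615 where 0). For cDNA between the lines the 495 became 1658 with a spread following the mean, 1448 with normexp and loess (68 higher, 1380 lower), 1133 with arrays scaled to one spread (137, 996), 178 with mode centring (117, 61), 305 without dim probes (129, 176), 174 with X centring (133, 41), 321 with at least 30 probes and 73 without high-input windows (18, 55). Leaving out 1 array gave 0 to 3028 (929 to 1593 where 0). Splits were 303 and 272 with 2 kb windows and 44 and 479 with 50 kb windows. H3K4me3 gave 54 in embryoid bodies and 8 after atRA with normexp, and 7 in embryoid bodies after subtracting core H3. Its other counts were 0, with 12 to 2159 windows at an unadjusted p under 0.05, and 0 in each fit that left out 1 array, with 19 to 1244. H3K27me3 in embryoid bodies went from 1 to 100 with normexp, 4 with one spread, 398 after subtracting core H3, 2 with the median over probes, 2 with 2 kb windows, 129 without high-input windows, and 0 with mode centring, X centring or 50 kb windows (511, 501 and 115 at an unadjusted p under 0.05), and to 46 to 428 without 1 array. H3K27me3 after atRA went from 4 to 71 with normexp, 21 with one spread, 150 after subtracting core H3, 18 with the median over probes, 58 without high-input windows and 93 within 1 extraction day, and to 26 to 361 without 1 array. It was 0 with a spread following the mean, mode centring, no dim probes, X centring, 2 kb and 50 kb windows and at least 30 probes, with 41 to 1045 at an unadjusted p under 0.05. H3K27me3 between the lines went from 3 to 8 with one spread, 14 within 1 extraction day, 3 to 22 without 1 array, and 0 with mode centring, no dim probes, X centring, 2 kb and 50 kb windows and at least 30 probes, with 59 to 832. The extraction day as a block tells nothing about a day effect. For H3K27me3 the day is the same split as embryoid bodies against the rest, which is already fitted, and for H3K4me3 the block amounts to leaving out undifferentiated LF2. For cDNA it left no residual degrees of freedom. A fit without 1 array has 1 residual degree of freedom, and the other array of that condition then adds nothing to the line difference. Apart from that, the cause was not tested.

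The female minus male change of H3K27me3 was -0.094 with normexp, -0.005 after subtracting core H3 and -0.217 without high-input windows. That of H3K4me3 was -0.681 with normexp, -0.064 without dim probes, -0.351 after subtracting core H3 and -0.299 with 2 kb windows, and its sign turned with one spread (1.049) and mode centring (0.026). For cDNA it was -0.157 with normexp and -0.214 without dim probes. For RNAPII it was 0.040 without dim probes, and its sign turned with normexp (-0.041), one spread (-0.025), mode centring (-0.077), X centring (-0.047) and 2 kb windows (-0.018). For H3K36me3 it was 0.052 with mode centring and 0.059 without dim probes, and its sign turned with X centring (-0.004). No 50 kb window met the H3K4me3 level. In single windows the sign turned for H3K4me3 with normexp at 99.65 Mb (-0.77), 100.18 Mb (-0.17), 137.92 Mb (-0.53), 152.83 Mb (-0.46) and 154.87 Mb (-0.38), and with one spread at 95.09 Mb (0.57), 100.61 Mb (1.02), 102.39 Mb (1.05), 155.48 Mb (1.5) and 164.01 Mb (0.76), and for cDNA at 99.66 Mb with one spread (-0.18). The causes were not tested. Over the named windows 502 values stayed, 81 lost their call, 10 gained one, 45 untested values moved by more than 2 times the median residual standard deviation and 11 turned. Those that stayed include settings that leave a window's own values unchanged, such as the deposited ratios.

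No paired analysis was possible because each group has 1 array and its number carries no pairing, other than by cell line, within which the tests of atRA and embryoid bodies already compare. Alternatives on exons, promoters, gene bodies and gene lists were not run. Random-sequence probes reach a large part of the X signal on each array, which limits how far a ratio can depart from 0.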

Other observations

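All tests and comparisons given here were chosen only after the results were seen.

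From 99.66 to 99.69 Mb, 30 kb next to the window that gained H3K27me3, LF2 embryoid bodies had a cDNA ratio 1.45 to 1.84 log2 above that of E14 embryoid bodies in each of 3 windows. The lowest of these differences lies above 99.95% of the 6512 windows in which the E14 input is at most 0.5 log2 above that of LF2, a description of these 2 arrays and not a test. RNAPII over the 3 windows was 1.32 in undifferentiated LF2 cells and 0.51 in their embryoid bodies, against 0.44 and 0.08 in E14, while the standard deviation over windows was also lower on the RNAPII embryoid body arrays (0.147 and 0.153) than on the undifferentiated ones (0.292 and 0.309). H3K27me3 over them was -0.10 in LF2 and -0.03 in E14 embryoid bodies.

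The window at 99.65 Mb, in which H3K27me3 rose, also had TBP at 2.03 in undifferentiated E14 cells and 1.00 in their embryoid bodies, and 1.24 and 0.54 in LF2. RNAPII there was 1.51 and 0.93 in E14, and 1.91 and 1.45 in LF2. H3K36me3 was 0.73 and -0.40 in E14, and 0.23 and -0.28 in LF2.

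H3K9me2 over the upper tercile of windows by mean cDNA ratio was -0.21 in undifferentiated E14 cells, -0.11 after atRA and 0.14 in embryoid bodies. In LF2 it was -0.10, 0.00 and 0.03. Over the lower tercile it was 0.14, 0.09 and 0.02 in E14 and 0.18, 0.05 and -0.06 in LF2. Its embryoid body arrays were extracted on another day than its other 4 arrays, so day and condition cannot be told apart, and the direction of its ratios rests on the dyes stated in the labels.

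The 6 arrays of an assay can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For cDNA 1 of the 10, the division by line, gave as many as 495 windows, and the highest other gave 0. For H3K4me3 the division by line gave 0, which all 10 reach of necessity, and the highest other was 427, with undifferentiated LF2 grouped with E14 atRA and E14 embryoid bodies. For H3K27me3 3 of the 10 gave as many as the real 3 windows, and the highest other count was 303, in 2 divisions that, given the condition term, both set only the undifferentiated arrays of the lines apart. For H3K27me3 a count that far above the real one points to a structure of the arrays. The 303 rests on 1 undifferentiated array per line, so no difference between the lines can be read from it. Within the 1 extraction day shared by the undifferentiated and atRA arrays, 14 windows differed in H3K27me3 between the lines.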
